A study of Drosophila melanogaster with 9 samples.

How the data were processed

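RNA-seq and small RNA sequencing data from adult Drosophila melanogaster were used. The RNA-seq covered testes of flies lacking the miR-310 cluster (4 neighbouring microRNA genes, miR-310 to miR-313) and of control flies, with 2 libraries each; both lines were derived from the same P-element stock, per the labels. Small RNA sequencing covered ovaries and testes of the strains Canton-S and Z56 and the carcass of Canton-S, with 1 library per strain and tissue. The flies were 3 to 5 days old and kept at 25 °C. RNA was extracted with Trizol, per the labels' protocols. The labels do not say whether libraries of a group came from separate dissections, so p-values measure only the spread between these libraries, which may be technical.

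For RNA-seq, the authors deposited log2(RPKM) values per gene with marks for genes that TargetScan predicts as targets of miR-313-3p or miR-313-5p, per the file headers and the series text. TopHat is named in the submitters' processing notes; its version, the counting tool and the genome build are not given in the sources used here. The table held 7539 genes, all above a log2(RPKM) of 1 in each of the 4 libraries (lowest value 1.00), so genes that fell below that level in any library were not analysed here. The sorted columns differed by at most 0.044 on the log2 scale, the pattern that quantile normalization leaves, and 3 genes had identical values in all 4 libraries. No read counts could be recovered from such values, so the RNA-seq depth is unknown. There were 114 profiles shared by 239 genes, as for overlapping or dicistronic genes, and such genes cannot be told apart. Whether counting used strand is not given, so genes and antisense partners may share reads. The 3 features whose names were whole numbers were kept as given.

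For small RNAs, the authors deposited read counts per mature microRNA and precursor together with RPM, reads scaled to a common library total; the deposited RPM differed by at most 0.005 from the count divided by the column total. Canton-S testes reads had been trimmed, masked and collapsed before mapping, per the series text. The 476 rows hold some mature sequences at several precursors. Rows of 8 names were therefore merged, taking the highest count, which left 465 mature microRNAs. Merged totals were 1394265 reads for Canton-S testes, 398044 for Canton-S ovaries, 1376516 for Z56 testes, 680094 for Z56 ovaries and 12306695 for Canton-S carcass. The upper limit that a count of 0 allows, 3 reads per library, corresponds to 2.15, 7.54, 2.18, 4.41 and 0.244 RPM in that order. Shares of single libraries carry exact Clopper-Pearson 95% intervals and ratios of 2 libraries carry exact conditional 95% intervals. Both cover counting error only, since PCR copies are not independent molecules.

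Mutant and control testes were compared with limma 3.58.1 in R 4.3.3 (eBayes with trend, prior degrees of freedom 3.46) on the deposited log2 values, with a planned minimum mean log2(RPKM) of 0, which removed no gene, and a Benjamini-Hochberg adjusted p threshold of 0.05. Fold changes are on the log2(RPKM) scale without a pseudocount. Target sets and gene lists were tested with camera, in both directions, at a preset inter-gene correlation of 0.01, with the estimated correlation beside it; fry tests a set against no change and not against other genes. The size of a target shift is the median log2 change of targets minus the median of genes marked for neither arm, with a bootstrap 95% interval over genes, which treats genes as independent. The 17 gene lists, fixed before the data were examined, covered germline stem cells and spermatogonia, meiotic arrest regulators, spermatid differentiation, testis proteasome and mitochondria, Y-linked fertility genes, somatic cyst and hub cells, accessory gland, ejaculatory duct and bulb, fat body, muscle, hemocytes, heat shock, antimicrobial peptides, the microRNA and piRNA pathways, reported miR-310 cluster targets and cytoplasmic ribosomal proteins. The 11 lists with at least 5 measured members were tested. Of the gene IDs, 7408 matched the name table. Genes were named by rule: the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap, all measured reported targets, and up to 4 members per list with the smallest adjusted p. A list of digestive enzyme genes was added after the data were seen.

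Testes and ovaries were compared by edgeR 4.0.16 (TMM, glmQLFit and glmQLFTest, tissue with strain as a term) over microRNAs with at least 10 counts in at least 2 of the 4 libraries, which kept 182. The strains serve as the replicates of the tissue difference, so the strain-by-tissue difference has no replicate and no test. MicroRNAs were named if they were arms of the miR-310 cluster, among the 10 most abundant of a tissue, among the 8 largest folds per direction or in a fixed microRNA list. Relative to library totals, TMM moved the tissue difference by a median of -0.46 on the log2 scale. Arm usage is the 5p share of the 5p and 3p counts of a precursor with at least 50 counts in a library; the 15 precursors that share an arm sequence were left out. Precursors were named if in the miR-310 cluster or among the 8 nearest to a share of 50% in Canton-S testes with at least 200 counts.

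The limma, camera and edgeR comparisons were tested on simulated data, camera on miR-313-3p targets only, and the other tests were not. With 7539 genes drawn independently at the spread of the testis libraries and 200 changed, limma recovered 46.3% of genes changed by 0.5 on the log2 scale, 85.1% at 1 and 93.9% at 2, and 2.6% of its calls were false. A shift of 0.04 in the 486 marked miR-313-3p targets was found by camera in 100% of 50 runs, and no shift in 0% of 50. The genes of these runs were also independent, whereas the real targets had an estimated correlation of 0.0249. The runs therefore do not show how camera performs on correlated targets. MicroRNA counts were simulated in 1 run for the 182 microRNAs, 40 of them changed, and 175 passed the count filter. Among these, edgeR recovered 57.1% at a log2 fold of 2, 92.3% at 4 and 100% at 6. The draws had a single common dispersion and no strain effect. They therefore do not show recovery for microRNAs whose tissue difference varies between strains. Alternatives tried were filters, pseudocounts, scalings, the replicate number as a block, each library left out, other correlations, expression-matched genes, DESeq2 1.42.0 and other count minimums. A gene table of another assembly (Release 6 plus ISO1 MT) was used only for chromosome arms, and no coordinates are given.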

Results

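The series profiled RNA in testes of flies without the miR-310 cluster and of control flies, and small RNAs in reproductive organs. The RNA-seq comprised 4 testis libraries, 2 mutant and 2 control, and the small RNA data 5 libraries with 398044 to 12306695 microRNA reads. Pearson correlations across genes, which are not independent replicates, were 0.994 between the controls, 0.993 between the mutants and 0.983 to 0.988 across genotypes. The deleted hairpins were not analysed in the RNA-seq, so the mutant label was not checked against them.

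The first comparison asks which transcripts differ in testes without the cluster. The trypsin gene alphaTry had the largest rise, from a log2(RPKM) of 1.72 ± 0.43 (SD, n = 2) in control to 6.31 ± 0.50 (n = 2) in mutant testes. The antifungal peptide gene Drs rose from 4.16 ± 0.32 to 5.81 ± 0.02 and CG15742 from 4.04 ± 0.08 to 5.64 ± 0.01. The noncoding RNA MRE16 fell from 8.53 ± 0.23 to 5.84 ± 0.11, CR32660 from 6.42 ± 0.14 to 4.45 ± 0.13 and CR43298 from 4.78 ± 0.18 to 1.89 ± 0.43. The glutathione S-transferase gene GstD3 fell from 4.45 ± 0.15 to 2.38 ± 0.34. In limma, 113 genes differed at an adjusted p under 0.05, 41 higher and 72 lower in the mutant, and 37 differed by more than 1 on the log2 scale. All 113 had non-overlapping groups, as did 50.4% of all genes (33.3% by chance).

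Among the other large rises, CG42807 differed by 2.30 (SE 0.26, adjusted p 0.0295), CR46044 by 2.13 (SE 0.08, adjusted p 0.00284), CG11598 by 1.99 (SE 0.20, adjusted p 0.0243), CG2941 by 1.73 (SE 0.08, adjusted p 0.00284) and CG5466 by 1.44 (SE 0.13, adjusted p 0.0184). CR45950 and CR43455, which have one shared profile, both differed by 1.81. The remaining large falls were CG44044 by -1.72, Sclp by -1.60, CR45547 by -1.60, CR45630 by -1.50, Pcd (pterin-4a-carbinolamine dehydratase) by -1.41 and CR43849 by -1.36, with adjusted p between 0.00324 and 0.0436. Adjusted p was 0.0062 for alphaTry, 0.0167 for Drs, 0.00284 for CG15742, MRE16 and CR32660, 0.00977 for CR43298 and 0.0143 for GstD3. Of these 20 genes, 12 stayed called whichever library was left out. The other 8, CG42807, CG5466, CG11598, Drs, GstD3, CR45630, Pcd and CR43849, lost their call in at least one such fit, with adjusted p from 0.0513 to 0.165. The count of called genes was 22 without control replicate 1 (14 higher and 8 lower; 20 of the 22 among the 113), 34 without control replicate 2 (16 and 18; 28 among the 113), 26 without mutant replicate 2 (8 and 18; 24) and 99 without mutant replicate 1 (40 and 59; 53), so the excess of falls did not hold in each.

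**Figure D1:**
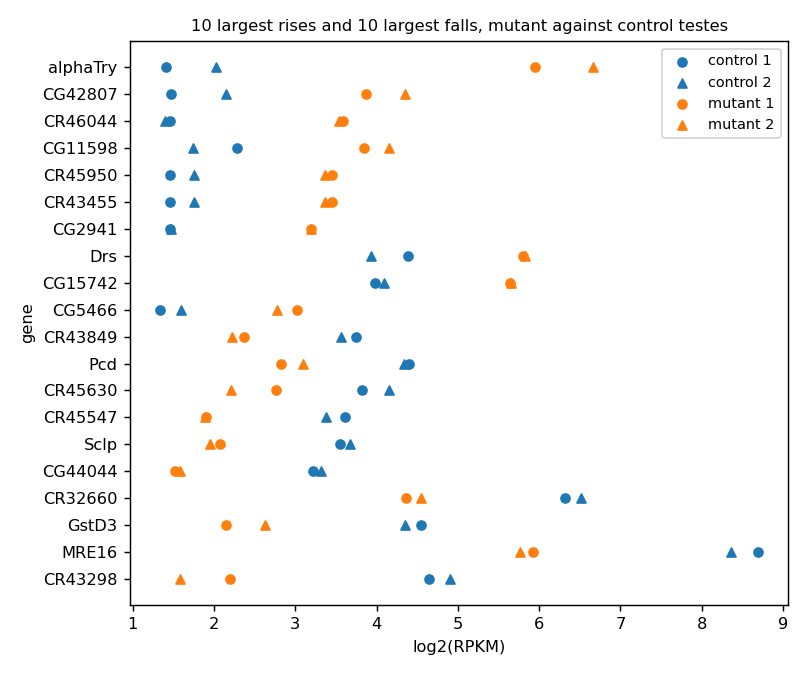
Log2(RPKM) (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall (vertical axis), with 1 point per testis library. For alphaTry the controls lie at 1.41 and 2.02 and the mutants at 5.95 and 6.66; for MRE16 the controls lie at 8.69 and 8.36 and the mutants at 5.92 and 5.76.

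Genes with CR names, given to noncoding RNAs, were over-represented among the called genes. Of 662 tested, 32 changed, 27 lower and 5 higher in the mutant, or 4.83% against 1.18% of other genes (Fisher's exact test, two-sided, p = 1.16e-09). The 5 higher ones were CR46044, CR45950, CR43455, CR45197 (a difference of 0.73) and CR31429 (0.66), the last 2 named after their values were seen. This class was chosen for the test after the gene names were seen, and CR46044 is an antisense RNA whose reads cannot be separated from its partner gene without strand.

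Antimicrobial peptide genes, the effectors of humoral immunity, lay higher in the mutant as a group. All 6 measured members had positive differences with a median of 0.82, and Drs and Dro rose (2 called over all genes, 3 adjusted over the list alone). Dro went from 3.03 ± 0.10 to 4.05 ± 0.18 (SD, n = 2 each) with an adjusted p of 0.027, while AttC (2.58 ± 0.83 to 4.22 ± 0.17), adjusted p 0.115, and CecA1 (a difference of 0.42), adjusted p 0.374, did not pass. The list passed camera with an adjusted p of 0.000493 and did not with an estimated correlation (adjusted p = 0.922 with an estimated correlation; fry, which tests a set against no change and not against other genes, p 0.0746). A list of digestive enzyme genes was written after alphaTry was seen, so the camera p of this list (1.13e-05, and 0.239 with an estimated correlation) is not a test of its rise. Of the 9 genes measured, 8 had positive differences, with a median of 1.13, and alphaTry and the lysozyme gene LysD (4.51 ± 0.07 to 5.50 ± 0.30, adjusted p 0.0458) were called. The median was 1.77 without mutant replicate 1 and 0.52 without mutant replicate 2. The amylase gene Amy-p stood at 1.46 and 2.06 in control and at 3.05 and 4.40 in mutant libraries (adjusted p 0.119). LysD has near-identical paralogs, and LysE differed by -0.0027 and the mannosidase gene LManII by 0.038. Dro lost its call without control replicate 1 (adjusted p 0.0882), control replicate 2 (0.124) or mutant replicate 2 (0.0752), while the list passed in all 4 such fits at the preset correlation, with adjusted p from 5.24e-08 to 0.0104, and in none with an estimated one (adjusted p from 0.72 to 0.979).

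Transcripts of the male reproductive tract differed in single genes. Of 25 listed accessory gland genes, 24 were measured in these testis libraries. How much tract tissue each library held was not examined, so such differences need not be those of testis cells. SP, the sex peptide of the accessory gland, fell from 10.96 ± 0.09 to 10.20 ± 0.12 (SD, n = 2 each; adjusted p 0.0314), and its call was lost without control replicate 1 (adjusted p 0.118) or control replicate 2 (0.0867). The list of 24 measured accessory gland genes had a median difference of 0.0043, with 1 call over all genes and 3 adjusted over the list alone, and camera gave an adjusted p of 0.986. Without mutant replicate 1 the median of this list was 0.15, and without mutant replicate 2 it was -0.12. The median near 0.0043 thus averages mutant libraries that differed from control in opposite directions. Acp76A differed by 0.66, lectin-46Cb by -0.45 and Acp32CD by -0.48, none of them called. Among ejaculatory duct and bulb genes, Peb stood at 5.55 in control replicate 1, 2.23 in control replicate 2, 1.79 in mutant replicate 1 and 1.03 in mutant replicate 2; without control replicate 2 its difference of -4.14 passed (adjusted p 0.0175), and PebIII differed by -0.41 and Est-6 by 0.57, both not called. Adh, the alcohol dehydrogenase and the only measured fat body gene, rose from 3.43 ± 0.10 to 4.30 ± 0.12 (SD, n = 2 each; adjusted p 0.0251), shares its profile with Adhr, and lost its call without either control replicate or mutant replicate 2 (adjusted p 0.0779, 0.115 and 0.0871).

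Stages of the male germ line showed few single-gene differences. For the unadjusted counts below, 1331 of all 7539 genes had an unadjusted p under 0.05 in limma. The testis proteasome gene Rpt4R fell from 4.46 ± 0.03 to 4.01 ± 0.04 (SD, n = 2 each; adjusted p 0.0458), the only call among 16 members of its list (also 1 adjusted over the list alone; camera adjusted p 0.62), and it lost that call when any 1 library was left out (adjusted p 0.0988 to 0.237). Rpt6R differed by 0.12, Rpt3R by -0.13 and Prosbeta2R1 by -0.10. Of 14 meiotic arrest genes, which regulate the spermatocyte transcription programme in either direction, none was called by limma over all genes (3 at an unadjusted p under 0.05). After adjustment over the list alone 1 was called. The gene tomb differed by -0.42, wuc by -0.39, achi by -0.16 and mia by 0.33, and camera gave an adjusted p of 0.283. None of 26 spermatid differentiation genes was called by limma over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05, camera adjusted p 0.58), with Mst98Cb at 0.27, boly at 0.21, Mst98Ca at 0.20 and janB at -0.67. The 7 measured genes of stem cells and spermatogonia had no call under either adjustment and 0 members at an unadjusted p under 0.05, with CycB and tut both at 0.18, nos at -0.19 and vas at -0.08 (camera adjusted p 0.673). For the 5 somatic cyst and hub genes camera gave an adjusted p of 0.62, with no call under either adjustment and 1 member at an unadjusted p under 0.05; shg differed by -0.21, so by 0.18 and Stat92E by -0.07. The Y-linked genes ARY and Pp1-Y2 differed by 0.14 and -0.08.

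Small RNA pathway, stress and housekeeping genes were likewise not called by limma, over all genes or adjusted over their lists alone. At an unadjusted p under 0.05 stood 0 genes of the microRNA pathway, 1 of the piRNA pathway, 1 heat shock gene and 8 ribosomal protein genes, against 1331 of all 7539 genes. In the microRNA pathway list (10 genes, camera adjusted p 0.947), gw, a component of the silencing complex, differed by 0.18 and pasha by 0.14. This list also holds Dcr-2 (-0.20) and r2d2 (-0.14), which belong to the small interfering RNA pathway. In the piRNA pathway (9 genes, camera adjusted p 0.62), armi differed by -0.22, krimp by 0.22, squ by -0.15 and aub by -0.08. Heat shock genes (12 genes, camera adjusted p 0.62) included Hsp68 at 0.31, Hsp27 at -0.08 and Hsp83 at 0.08, and Hsp70Bbb stood at 2.43 in mutant replicate 2 against 1.32 to 1.40 in the other 3 libraries. Without mutant replicate 1 the heat shock list passed, with a median of 0.26 and an adjusted p of 0.000112 (0.765 with an estimated correlation), and Hsp70Bbb passed (adjusted p 0.0357). The 92 cytoplasmic ribosomal protein genes had a median of -0.0055 (camera adjusted p 0.659). Their median was -0.07 without mutant replicate 2 and -0.053 without control replicate 2. It was 0.058 without mutant replicate 1 and 0.071 without control replicate 1. Among them RpL30 differed by -0.41, RpL34b by -0.27, RpL7-like by -0.35 and RpL32 by -0.24. The muscle genes Act57B, Mlc1 and Mlc2 differed by 0.09, -0.06 and 0.08, and the hemocyte gene crq by 0.02.

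The second comparison asks whether predicted targets of the cluster differ in the mutant. The table marks 486 genes as miR-313-3p targets, 241 as miR-313-5p targets and 43 as targets of both. The 3p arms of the cluster have a common seed, so a miR-313-3p target is in general also a predicted target of miR-310-3p, miR-311-3p and miR-312-3p. Targets of miR-313-3p lay higher in the mutant by a median of 0.037 on the log2 scale (bootstrap 95% interval 0.0199 to 0.0579) relative to genes marked for neither arm, and 61.1% of them had a positive difference against 50.4% of the 6855 other genes. The shift was positive in all 4 pairs of a mutant and a control library (0.0346 to 0.0521), while between libraries of one genotype it was 0.0026 (control replicate 2 minus 1) and -0.0103 (mutant replicate 2 minus 1). Camera gave p = 0.00915, 0.0275 after adjustment over the 3 target sets, and p = 0.222 with an estimated correlation; fry, which does not compare the targets with other genes, gave p = 0.0795.

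Targets of miR-313-5p, the abundant arm of that precursor, lay higher by 0.018 (0.00435 to 0.0394), with 58.9% positive and 3 of 4 library pairs positive, which did not pass camera (p = 0.221; 0.71 with an estimated correlation). Without mutant replicate 2 the shift of the 5p targets (n = 241 genes) was 0.038, and without mutant replicate 1 it was 0.0020. Targets of both arms lay higher by 0.0073 (-0.025 to 0.0545; camera p = 0.557; 0.788 with an estimated correlation). Targets of both arms differed from the 641 targets of a single arm by -0.029 in the median (permutation of genes, two-sided p = 0.252). Single marked genes were not called more often than others. Of the 3p targets 6 changed, or 1.23% against 1.52% of other genes (Fisher's exact test, p = 0.846), and of the 5p targets 1 changed (p = 0.271). The 6 were CG2233 (1.39), CG5466 (1.44) and CG12729 (0.50), higher, and CG30080 (-0.81, a target of both arms), DOR (-0.69) and CG12521 (-0.61), lower; all but CG5466 were named after their values were seen. Among targets reported for the cluster, the beta-catenin gene arm differed by -0.10 ± 0.08 (SE), the kinesin gene Khc-73 by 0.10 ± 0.09 and the nuclear receptor gene Hr96 by 0.08 ± 0.10, none called.

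**Figure D2:**
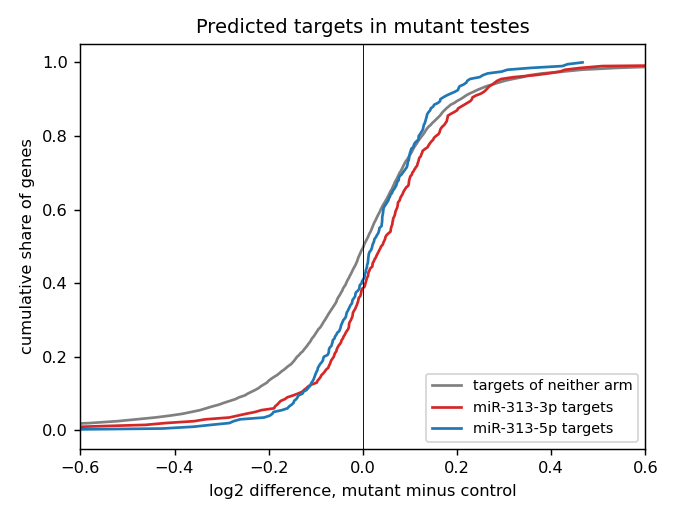
Cumulative share of genes (vertical axis) against the log2 difference between mutant and control testes (horizontal axis, shown from -0.6 to 0.6) for miR-313-3p targets, miR-313-5p targets and genes marked for neither arm. The median lies at 0.0387 for 3p targets, 0.0199 for 5p targets and 0.0016 for the others.

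The third comparison asks which microRNAs distinguish testes from ovaries. Testes carried clusters that were nearly absent from ovaries. miR-985-3p had 32221 reads in Canton-S testes and 1 in ovaries (ratio of RPM 9199, 95% counting interval 1651 to 363339), and 17876 against 0 in Z56 (lower 95% counting bound 2394-fold). miR-974-5p had 3786 and 4381 reads in testes and none in either ovary library (lower bounds 293-fold and 587-fold). miR-375-3p was 394-fold and 524-fold higher, and miR-959-3p 373-fold and 500-fold. Ovaries carried miR-994-5p at 8378 and 10691 RPM against 1 read in each testis library, and miR-989-3p at 43897 and 73378 RPM against 1592 and 118 RPM in testes.

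In edgeR, 81 of 182 tested microRNAs differed, 67 higher and 14 lower in testes; the DESeq2 Wald test called 86, 61 higher and 25 lower. The count was 26 without Canton-S testes, 29 without Z56 testes, 63 without Canton-S ovaries and 60 without Z56 ovaries, in fits without a strain term. All 12 arms of the miR-959 to miR-964 cluster were higher in testes (12 also adjusted over the list alone), as were all 11 tested arms of miR-972 to miR-979 (11). So were 10 of 11 tested arms of the cluster of miR-303 and miR-982 to miR-985 (11 adjusted over the list alone). All 5 tested arms of the miR-991 and miR-992 cluster were higher as well (5). Here and below, the cluster of miR-303 and miR-982 to miR-985 also counts miR-2499, and the miR-991 and miR-992 cluster also counts miR-2498. Together the cluster of miR-303 and miR-982 to miR-985 made up 5.59% of microRNA reads in Canton-S and 4.78% in Z56 testes, against 0.0093% and 0.0485% in ovaries. The miR-959 to miR-964 cluster made up 3.49% and 3.84% of testis reads. Other large testis folds were miR-991-3p (1374-fold and 221-fold), miR-964-5p (106-fold and 404-fold), miR-982-5p (482-fold and 79.3-fold) and miR-959-5p (165-fold, interval 45.7 to 1368, and 261-fold, interval 89.0 to 1266).

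Toward ovaries, the miR-318 and miR-994 cluster (3 of 3 tested arms called, 3 adjusted over the list alone) and both arms of miR-989 (2) were lower in testes. miR-318-3p had 249 and 193 reads in ovaries against 0 and 2 in testes. Adjusted p was 0.00755 for miR-994-5p, 0.0159 for miR-318-3p, 0.0384 for miR-989-3p and 0.0143 for miR-989-5p; both miR-989 arms lost their call without Canton-S ovaries (0.0878 and 0.118) or Z56 ovaries (0.118 and 0.0597). miR-184-3p, the most abundant ovary microRNA at 39.3% and 44.7% of reads, was 4.44-fold and 7.13-fold higher in ovaries (adjusted p 0.0192). miR-92b-3p, a relative of the cluster with the same seed, was 13.4-fold and 4.47-fold higher in ovaries (adjusted p 0.0193; 0.0671 without Canton-S testes). The other relative, miR-92a-3p, was 16.2-fold and 1.55-fold higher there and not called in the main fit (adjusted p 0.0966). It was called with DESeq2 size factors (0.00627), by the DESeq2 Wald test (0.00157), without a count filter (0.0306), without a strain term (0.0427) and with rows as deposited (0.00658). In the list of these relatives, 1 of 3 tested arms was lower in testes over all microRNAs and 3 adjusted over the list alone. miR-9c-3p was 6.71-fold and 11.1-fold higher in ovaries (adjusted p 0.0192) and lost its call in 3 of the 4 fits without a library, with adjusted p from 0.0626 to 0.112. Of the locus of miR-9b, miR-9c, miR-306 and miR-79, 3 of 6 tested arms were lower in testes (4 adjusted over the list alone). These were miR-9c-3p, miR-9c-5p (adjusted p 0.02) and miR-9b-5p (adjusted p 0.0373).

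Among microRNAs of many tissues, the muscle microRNA miR-1-3p was the most abundant in testes (19.0 ± 1.12% of reads; SD over the 2 strains) and in carcass (53.1%), against 7.83 ± 0.28% in ovaries, and was not called (adjusted p 0.145); on library totals it was called (0.0169). let-7-5p made up 13.4 ± 0.28% of testis and 2.89 ± 0.41% of ovary reads (adjusted p 0.0382; 0.0867 with DESeq2 size factors and 0.199 without a count filter), and 4 of 6 arms of the let-7 complex were higher in testes over all microRNAs and over the list alone. miR-34-5p was 5.57-fold and 8.33-fold higher in testes (adjusted p 0.0193; 0.0663 without a count filter), one of 2 arms of the miR-277 and miR-34 locus called out of 6 (1 adjusted over the list alone). miR-31b-5p was 8.10-fold and 12.0-fold and miR-10-3p 16.4-fold and 13.8-fold higher in testes, both with an adjusted p of 0.0187. miR-31a-5p, miR-275-3p, miR-263a-5p, miR-33-5p, miR-279-3p, miR-8-5p, miR-8-3p and miR-276a-3p, also among the most abundant of a tissue, were not called in the main fit. The DESeq2 Wald test called miR-31a-5p (adjusted p 9.25e-06) and miR-263a-5p (1.44e-06). Without a strain term edgeR called miR-31a-5p (0.0436), miR-263a-5p (0.0219) and miR-275-3p (0.0404). miR-133-3p, with 34 and 37 reads in testes and none in ovaries, was the call of the muscle list (1 of 2 tested). miR-124-3p was the call of the nervous system list, with 69 and 346 testis reads against 4 and 7 (1 of 5 tested, 0 adjusted over the list alone). Of 42 tested arms of broadly expressed microRNAs, 2 were higher and 4 lower in testes, and none was called adjusted over the list alone. The single tested arm of the miR-309 cluster, miR-5-5p, had an adjusted p of 0.772.

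**Figure D3:**
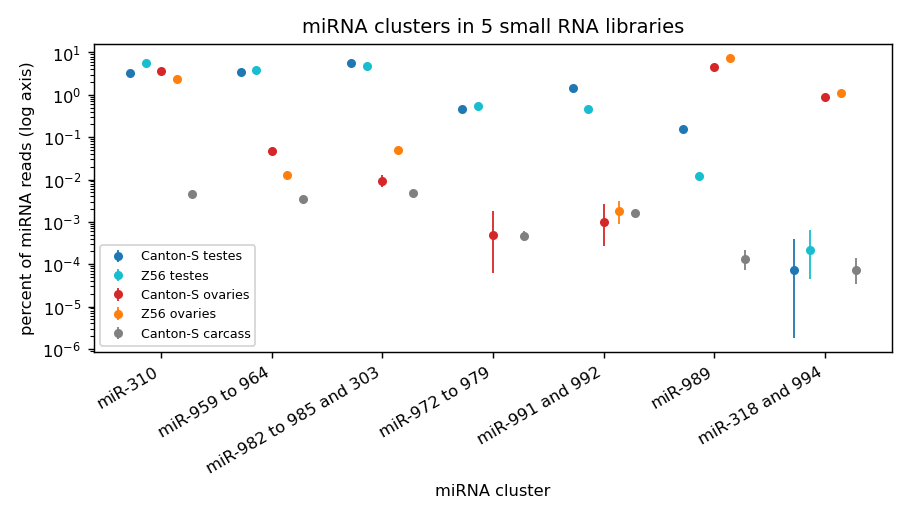
Percent of microRNA reads (vertical log axis) taken by 7 microRNA clusters (horizontal axis) in the 5 small RNA libraries, 1 point per library, with exact 95% binomial intervals; libraries with no read of a cluster have no point. The cluster of miR-303 and miR-982 to miR-985 reaches 5.59% and 4.78% in testes, and miR-989 reaches 4.42% and 7.34% in ovaries.

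The fourth comparison asks where the miR-310 cluster is expressed. It took 3.31% of microRNA reads in Canton-S testes (95% interval 3.28 to 3.34), 3.59% in Canton-S ovaries (3.53 to 3.65), 5.60% in Z56 testes (5.56 to 5.64) and 2.42% in Z56 ovaries (2.38 to 2.45). In Canton-S carcass it took 0.00448% (0.00411 to 0.00487), which is 739-fold less than in testes (interval 679 to 805) and 802-fold less than in ovaries (737 to 875). These intervals hold counting error only, and the shares depend on the most abundant microRNA: without it in each library the carcass was 424-fold under testes and 620-fold under ovaries. miR-312-3p was the main product in all 5 libraries, at 20749 and 25674 RPM in Canton-S and Z56 testes and 22721 and 18058 RPM in ovaries. miR-313-3p was the rarest arm in testes, at 12.9 RPM (7.65 to 20.4) in Canton-S and 27.6 RPM (19.5 to 37.9) in Z56.

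The tissue difference of the whole cluster was not the same in both strains. In Canton-S the cluster was 0.921 times as abundant in testes as in ovaries (0.904 to 0.938), and in Z56 2.32 times (2.28 to 2.36); without the most abundant microRNA of each library the ratios were 0.684 and 1.60. Of its 8 arms, miR-312-5p was higher in testes in edgeR (log2 difference 1.92, adjusted p 0.04), with 5.62-fold and 4.84-fold higher RPM in the strains; adjusted p was 0.0575 with DESeq2 size factors, 0.106 without a count filter, 0.0711 with rows as deposited, and 0.0916 to 0.115 without Canton-S testes, Canton-S ovaries or Z56 ovaries. None of the 8 arms was called adjusted over the list alone. miR-313-3p was not called in the main fit (adjusted p 0.296). It was called lower in testes with DESeq2 size factors (0.0285) and with rows as deposited (0.0165). Its RPM in testes was 0.101 times that in ovaries in Canton-S and 2.09 times in Z56. The sign of the fitted difference of miR-310-5p, miR-312-3p and miR-313-5p turned with the scaling. miR-311-5p was 1.83-fold and 2.40-fold higher in testes, miR-310-5p 1.71-fold (1.21 to 2.48) and 1.12-fold (0.804 to 1.57), and miR-313-5p 1.02-fold (0.927 to 1.13) and 1.89-fold (1.77 to 2.03). miR-310-3p was 2.38-fold higher in ovaries in Canton-S (2.25 to 2.51) and 12.1-fold higher in testes in Z56 (11.2 to 13.0).

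**Figure D4:**
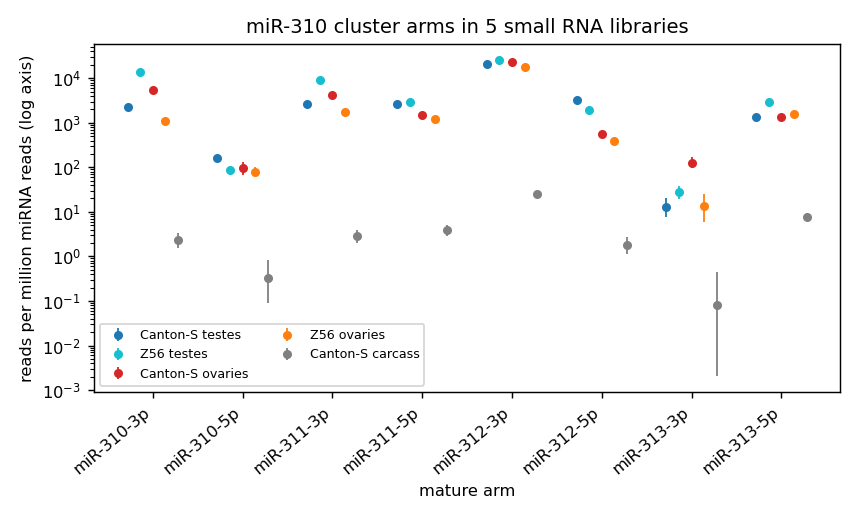
RPM of microRNA reads (vertical log axis) of the 8 mature arms of the miR-310 cluster (horizontal axis) in the 5 small RNA libraries, 1 point per library, with exact 95% binomial intervals. In carcass no arm exceeds 25.8 RPM, and miR-312-3p stands between 18058 and 25674 RPM in the gonads.

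The fifth comparison asks how the 2 arms of a precursor are used. In Canton-S testes, the 5p arm made up 6.65% of mir-310 reads (95% interval 5.84 to 7.54), 50.7% of mir-311 (49.5 to 51.8), 13.4% of mir-312 (13.0 to 13.8) and 99.0% of mir-313 (98.5 to 99.4). In Z56 testes the shares were 0.654%, 24.3%, 6.96% and 99.1%. In ovaries they were 1.72%, 26.0%, 2.45% and 91.1% in Canton-S and 6.64%, 40.7%, 2.15% and 99.2% in Z56. The mir-313 precursor thus gave mostly its 5p arm in all 4 gonad libraries and in carcass (99.0%), while mir-310 and mir-312 gave mostly 3p. The 5p share of mir-312 was higher in testes than in ovaries in both strains, by 10.9 and 4.81 percentage points.

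Beyond the cluster, 32 of 87 precursors in Canton-S testes had at least 10% of their reads on the minor arm (36.8%), 28 of 88 in Z56 testes (31.8%), 10 of 52 in Canton-S ovaries (19.2%), 14 of 53 in Z56 ovaries (26.4%) and 32 of 100 in carcass (32.0%). Among precursors with at least 200 counts, those nearest to equal use in Canton-S testes, besides mir-311, were mir-963 (54.5% 5p), mir-965 (57.2%), mir-9369 (39.2%), mir-92a (39.2%), mir-100 (38.9%), mir-2498 (38.7%) and mir-8 (37.9%). mir-963 gave 95.9% 5p in Z56 testes and mir-92a 24.2%, whereas mir-9369 gave 39.4% and mir-8 38.3%. Of 47 precursors with at least 50 counts in all 4 gonad libraries, 18 shifted the same way between tissues in both strains and 27 in opposite ways, while mir-1 and mir-5 (named after their values were seen) had a shift of 0 in at least 1 strain. The signs include shifts near 0, such as mir-184 at -0.0009 and 0.0015 points. At an adjusted p under 0.05 in both strains (Fisher's exact test on reads, counting error only), 4 shifted in opposite ways. By the same test mir-312, mir-8, mir-283, mir-986, mir-988 and mir-995 shifted the same way. Of the precursors named here, all but mir-312 and mir-8 were picked out after their values were seen. Shifts of over 10 points in both strains went the same way in 2, mir-283 (-21.4 and -33.2 points, testes minus ovaries) and mir-988 (-16.7 and -11.2), and opposite ways in 4, mir-14 (22.97 and -13.76), mir-277 (20.2 and -12.6), mir-311 (24.7 and -16.4) and mir-965 (13.4 and -13.5), all but mir-311 and mir-965 named after their values were seen. With 1 library per strain and tissue these differences have no replicate check.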

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

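All tests in this part were chosen after the values were seen. The named items below moved in opposite directions between testes and ovaries in Canton-S and Z56, with counting intervals or an unadjusted Fisher's exact test past the threshold in both strains; with 1 library per strain and tissue the difference between strains was not tested.

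On the log2 scale, miR-310-3p was at -1.25 in Canton-S (testes minus ovaries) and 3.59 in Z56, a gap of 4.84; miR-311-3p was at -0.67 and 2.36, a gap of 3.03; and miR-312-3p was at -0.13 and 0.51, a gap of 0.64. For the 5p share of mir-310 the tissue difference was 4.93 points in Canton-S and -5.99 in Z56 (gap -10.9), and for mir-311 it was 24.7 and -16.4 (gap -41.1). Outside the cluster, miR-276a-3p was at -2.62 and 1.54 (gap 4.16), miR-33-5p at 0.045 and -0.54 (gap -0.59), and the 5p share of mir-965 at 13.4 and -13.5 points (gap -26.9; adjusted p 0.0526 in Canton-S). The cluster was not alone in its arm shares: after adjustment 4 precursors moved in opposite directions in both strains, mir-310, mir-311, mir-14 (22.97 and -13.76 points) and mir-305 (-7.24 and 5.37 points), the last 2 named after their values were seen.

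With 1 library per strain and tissue, gaps can only be held against their spread over other loci. A change in the output of the whole precursor would move both arms alike, which the values argue against as the whole cause for mir-310: its 5p gap (-0.62) minus its 3p gap lay under the median of 18 other precursors with an upper 95% bound of -2.11 by their spread, while for mir-311 (5p gap 0.38) that bound was 0.697 and this stays open. Reads moving between the similar 3p arms would leave their sum in place; no 3p arm fell (miR-313-3p had a gap of 4.37), but the gap of the sum, 1.54, had a lower 95% bound of -1.02 by the spread of 74 microRNAs outside the cluster (SD 1.31), so this stays open too. A library effect that reaches other loci also remains open: of these 74, all with at least 20 counts in each library, 4 had a gap at least as large as that of miR-311-3p (miR-276a-3p, miR-92a-3p, miR-2b-3p and miR-34-3p) and 1, miR-989-3p, as large a gap the other way (-4.50), all picked out after their values were seen, so the pattern is not restricted to the cluster and may come from the preparation of single libraries. A real difference between strains in 3p arm levels was not tested.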

How the results depend on the processing

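Of 81 values recomputed with all libraries in place, 70 were labelled as kept. Target shifts were kept if they held their direction and their side of the threshold, and shares if they stayed within counting error. Counts of called genes, gene lists or microRNAs were kept if they lay near the reported count, so a kept count may have moved. Kept counts include 81 genes without a trend in eBayes against 113. They also include 91 microRNAs with DESeq2 size factors and 98 with rows as deposited, against 81. The values not kept were the gene count with a replicate block, the 3p target shift and the gene lists with an estimated correlation, and shares of the miR-310 cluster. Across filters, pseudocounts and scalings, the number of genes changed in the mutant lay between 99 and 120, and without a trend in eBayes at 81. The filter at a mean log2(RPKM) of 0 removed no gene, so that comparison says nothing about stability. Median scaling and quantile normalization acted on sorted columns that already differed by at most 0.044. The largest shift of a library median was 0.00657, so these scalings could change little. Both kinds of comparison are counted among the 70 of 81. With the replicate number as a block, 238 genes were called, among them all 113. Whether the numbers pair the libraries is not given in the labels. The deviations of same-numbered libraries correlated at 0.0599, and the cause of the higher count was not tested. Of the 127 named or listed microRNAs 7, none of them called, changed sign with the scaling.

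Leaving out each testis library in turn assumes that the lone library of a group varies like the others. It gave 22 to 99 changed genes, a shift of 0.0330 to 0.0424 for miR-313-3p targets, 0.0020 to 0.0381 for miR-313-5p targets (passing without mutant replicate 2) and 0.0019 to 0.0265 for targets of both arms, and 1 to 3 gene lists. Fewer libraries give fewer degrees of freedom. With an estimated correlation the shift of miR-313-3p targets was still 0.0371, with a camera p of 0.222 over n = 486 genes, and 0 gene lists passed; the cause was not tested. Leaving out each small RNA library in turn gave 26 to 63 different microRNAs. These fits, the removal of shared profiles and the use of repeated rows were chosen after the data were seen.

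The share of the miR-310 cluster depends on the total it is taken of. Without the most abundant microRNA of each library it was 4.05% in Canton-S testes, 5.91% in Canton-S ovaries, 6.99% in Z56 testes, 4.38% in Z56 ovaries and 0.00955% in carcass. With repeated entries kept as deposited it was 3.27% in Canton-S and 5.53% in Z56 testes, and over microRNAs detected in every library of the strain 5.72% in Z56 testes. In all of these the total changed and the cluster counts did not, apart from arms not detected everywhere.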

Other observations

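The tests of chromosome spread and of gut tissue in this part were chosen after the results were seen. Reads of gonad microRNA clusters appeared in the carcass at a low level. For every 100 reads in Canton-S testes, the carcass library held 1.19 reads of the miR-310 cluster, 0.897 of the miR-959 to miR-964 cluster, 0.882 of miR-972 to miR-979, 0.744 of the cluster of miR-303 and miR-982 to miR-985 and 1.02 of the miR-991 and miR-992 cluster. These are raw counts, from 12306695 carcass and 1394265 testis reads; by share the miR-310 cluster was 739-fold lower in carcass. Within the miR-310 cluster, miR-313-5p stood apart with 5.07 carcass reads per 100 testis reads, against 1.096 for miR-312-3p and 0.906 for miR-310-3p; miR-313-3p had 1 carcass read and 18 testis reads. The relatives miR-92a and miR-92b outside the cluster stood at 56.8 with all arms counted, of which miR-92a-5p held 602 carcass and 545 testis reads. The 3p arms, which have the seed of the cluster, had 208 (miR-92a-3p) and 263 (miR-92b-3p) carcass reads against 847 and 494 testis reads. In Canton-S testes, miR-989-3p had 2220 reads while miR-994-5p, also lower in testes, had 1; the ovary library had 17473 and 3335.

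The changed genes of the mutant were unevenly spread over the chromosomes. On 2L 0.854% of tested genes were called (13 of 1522) and on 2R, the arm that holds the miR-310 cluster, 0.517% (8 of 1548), against 2.08% on the X (22 of 1057), 1.62% on 3L (24 of 1480) and 2.34% on 3R (43 of 1841). CR45199 was called on chromosome 4, and CG45764 and CG45765 on the Y, all named after their values were seen. The odds of a call on the X and the third chromosome were 3.01 times those on the second (95% interval 1.85 to 5.12, Fisher's exact test p = 1.13e-06). Uneven spread of expression levels and noncoding genes is argued against, since the odds ratio within 10 strata of both had a lower bound of 1.84. Noisier libraries for these chromosomes are also argued against, with an upper bound of 1.02 for the ratio of replicate differences. A candidate explanation is genetic background on the X and the third chromosome that mutant and control do not share. An unadjusted p under 0.05 was found for 18.6% of all tested genes there against 16.2% on the second chromosome, and among genes not called the odds ratio was 1.103 (0.971 to 1.25), but leaving out the called genes filters on the outcome, so this ratio decides nothing and the explanation stays open.

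The target shift was positive on both sides of this spread: miR-313-3p targets lay higher by 0.048 on the second chromosome (0.0207 to 0.0765, 194 genes) and by 0.028 on the X and the third (0.00647 to 0.0507, 289 genes). The difference between the shifts was not tested.

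The digestive enzyme genes that rose in mutant testes raise the question of carried-over gut. The digestive list was written after alphaTry was seen, and only alphaTry and LysD of its 9 genes were called. The differences were uneven between libraries: all 9 genes lay higher in mutant replicate 2 than in replicate 1. Their median difference from control was 1.77 without mutant replicate 1 and 0.52 without mutant replicate 2, although 7 had both mutants above both controls. A larger share of other reproductive tract tissue is argued against for the accessory gland only, whose median had an upper 95% bound of 0.079, under the digestive median of 1.13. That bound is a bootstrap over genes treated as independent and does not cover the spread between libraries. The accessory gland median was 0.15 without mutant replicate 1 and -0.12 without mutant replicate 2, also under the digestive medians of these fits. Carried-over gut tissue stays open: the 7 digestive genes that were not called had a median difference of 1.13 (6 higher, exact sign test p = 0.125) with LysE at -0.0027, but leaving out the called genes filters on the outcome, so this decides nothing. A response of the testis to the deletion stays open as well and was not tested, and gut genes under the level of the table were not analysed here.

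The 4 testis libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split called 113 genes and the highest of the other splits 0, so 1 of the 3 splits, the real one, gave as many.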
